A study of Mus musculus with 12 samples.

How the data were processed

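Single-cell RNA-seq libraries were made from dissociated mouse hippocampi with the 10x Genomics 3' v3.1 chemistry, with a target of 5000 cells each, and sequenced on a NovaSeq instrument, per the labels' protocols. Mice were perfused with cold buffer and the tissue was dissociated with an enzymatic kit, steps that can themselves induce immediate early and stress genes. Cell Ranger 5.0.0, Scanpy and the mouse build mm10 are named in the submitters' processing notes without roles or order, and the annotation release is not given in the sources used here. The 3' chemistry counts UMIs near transcript ends, so each value depends on the annotated ends and says nothing about isoforms.

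The matrix deposited by the authors holds raw UMI counts per cell and gene, whole numbers of at least 1 for 19834 cells and 32285 genes. Every cell carries the authors' library name, 1 of 12 cell types and 1 of 21 clusters, and these types are used as deposited. All cells have at least 500 genes in the authors' quality table, whose total is a signal deposited with decimals, with a median ratio of 1.019 of the summed counts to it. The authors' doublet score reaches 0.097, and no deposited cell is marked as a doublet, so no further doublet call was made. The authors' mitochondrial percent follows the 72 genes whose names start with Mt (r across cells 0.9999) and not the 13 mitochondrially encoded genes (r = −0.067), so those 13 were summed anew: 4868 cells (24.54%) exceed 10% of UMIs, and they were kept, since an alternative leaves them out. The authors' deposited mean per gene, a score, enters no test. Cells had a median of 5581 UMIs and 2146 genes.

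Counts were summed per library and cell type, because cells of 1 library are not independent replicates. A library with fewer than 10 cells of a type was left out of that type, and a type was tested where every group kept at least 2 libraries, which gave 9 types and left out ependymal cells, fibroblasts and progenitors. edgeR 4.0.16 in R 4.3.3 fitted a quasi-likelihood model to the sums, with TMM normalization, filterByExpr and the 4 groups plus the batch (replicate 1 against replicates 2 and 3) as terms, over all 12 libraries, which share 1 estimate of the spread. Deviations of log CPM from the group means were correlated between libraries of the same replicate number. For numbers 1, 2 and 3 they gave 0.532, 0.531 and 0.213 between Cisplatin nonstim and Cisplatin stim and 0.597, 0.249 and 0.442 between PBS nonstim and PBS stim, so the numbers were taken to pair the libraries within each drug arm. The pairing comes from the data and in part from the batch, which number 1 marks: within the second batch alone the correlations were 0.319 and 0.051. Of 6 libraries in each arm, 6 correlated best with their own number in the cisplatin arm and 4 in the PBS arm, where the pairing is weaker. The fit of cisplatin averaged over stimulation takes all 12 libraries as independent, so its p-values can be too small where such pairs deviate together. The comparisons were cisplatin without stimulation, stimulation in cisplatin mice, stimulation in PBS mice, their interaction and cisplatin averaged over stimulation. P-values were adjusted by Benjamini-Hochberg within a cell type and comparison, and a gene was called at an adjusted p under 0.05.

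The 24 gene lists, the comparisons, the tests and the rule for named genes were fixed before the data were examined. Each list with at least 5 tested members was tested with camera of limma 3.58.1 at a preset correlation of 0.01, with Benjamini-Hochberg over the 117 list and type pairs of a comparison. The same test with an estimated correlation and fry stand beside it. Numbers of called members are given over all genes tested and adjusted over the list alone. Shares of cell types were tested with edgeR on cell counts with the total of each library as offset, for 11 types, and by an exact permutation within batches.

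The rule names, in at most the 4 types with the most calls of a comparison, the 4 called genes with the smallest adjusted p in each direction, leaving out predicted genes named Gm with digits, Rik genes and clone names. Where a comparison makes under 10 calls every called gene is named. It adds the 2 to 4 members with the smallest p in the direction of each list that passes, and the 3 members with the smallest p of the myelin, disease-associated microglia, reactive astrocyte and p53 lists, as values whether or not they pass. Genes that mark another cell type are named with that said beside them. The text prints a selection of the genes this rule gives, and 1 gene called in the interaction is not reported here. Gm2000, Gm11808, Usp50, Gstp1, Scrg1, Rps27rt, Wdr89, Eno1b, the OPC and pericyte calls and the set of Rbm3, Cirbp, Gstm1, Hsp90b1, Dnaja1 and Hsp90ab1 lie at least in part outside it and were chosen after their values were seen, as were the ribosomal RNA-like transcripts.

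Genes that share sequence were marked by matching 31-base words over the last 500 bases of the transcripts of the GENCODE M21 annotation of GRCm38, the assembly mm10 is made from, by gene name for 31398 of the matrix's genes (97.3%). A gene with a share of at least 0.5 of its words in other genes is called a near copy. Gene positions come from the same annotation.

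Scripts were tested on simulated counts drawn from the real means and library sizes with 200 genes changed in both cisplatin groups and 200 others changed in Cisplatin stim. For cisplatin without stimulation in oligodendrocytes (9976 genes) 50.7, 71.6 and 97% of genes changed 1.5, 2 and 4-fold were called, and 16 unchanged genes. For stimulation in cisplatin mice 31.3, 76.1 and 90.9% were called, for the interaction 11.9, 56.7 and 87.9%, and for cisplatin averaged over stimulation 77.6, 91 and 98.5%. In endothelium the shares were 9, 65.7 and 92.4% for cisplatin without stimulation and 10.4, 26.9 and 78.8% for the interaction. A list raised in the cisplatin groups had an adjusted p of 1.29e-46 with 0 other lists called. A share lowered in the simulation was found with equal relative spread in all types (edgeR adjusted p = 3.17e-08) and missed where rare types had a larger spread (edgeR adjusted p = 0.12).

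Alternatives fixed beforehand were DESeq2 1.42.0, limma-voom, size factors of DESeq2, no filter on low counts, at least 30 cells, no batch term, the replicate number as a block, no cells above the 95th percentile of UMIs, no cells over 10% mitochondrial UMIs, and each library left out in turn. Added after the data were seen were the ribosomal RNA-like share as a covariate, each batch alone, near copies left out, and the PBS or Cisplatin stim libraries of the second batch left out. The alternative for values deposited in another unit does not apply, since the values are counts. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 read the matrix and drew the figures.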

Results

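Hippocampi of 9-week-old female C57/BL6J mice were dissociated into single cells after treatment with cisplatin, a platinum drug that crosslinks DNA, or with phosphate-buffered saline (PBS). In each arm some mice also received 40 Hz light flicker and sound, a sensory stimulation used to entrain gamma-band rhythms, for 1 h daily over 21 days, and all tissue was taken on day 22. The 4 groups, named PBS nonstim, PBS stim, Cisplatin nonstim and Cisplatin stim as in the labels, had 3 libraries each. Replicate 1 of each group was made from 2 hippocampi of 1 animal and replicates 2 and 3 from 4 hippocampi of 2 animals. The library names carry the prefix 20 for the 4 replicate 1 libraries and 21 for the other 8, and these are called the first and the second batch here.

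The 12 libraries held 19834 cells, with 611 to 2772 cells and 3964338 to 17656020 unique molecular identifiers (UMIs) per library. PBS nonstim, PBS stim, Cisplatin nonstim and Cisplatin stim held 5989, 4868, 5749 and 3228 cells. The authors' annotation put 4677 cells in oligodendrocytes, 4530 in microglia, 3233 in choroid plexus, 2622 in astrocytes, 1434 in endothelium, 1074 in neurons and 894 in oligodendrocyte precursors (OPCs). The remaining 549 immune cells, 379 pericytes, 197 progenitors, 173 ependymal cells and 72 fibroblasts were fewer. Mitochondrially encoded transcripts took a median of 10.7 to 17.6% of the UMIs per cell in the libraries of the first batch and 3.19 to 5.12% in those of the second. Gm42418 and AY036118, which overlap ribosomal RNA sequence, and Lars2, which varied with them, are grouped here as ribosomal RNA-like transcripts, a set chosen after the values were seen. They made up 1.87 to 3.65% of all UMIs in the 4 PBS libraries of the second batch. Their share was 0.417 to 0.782% in the 4 cisplatin libraries of that batch, 0.479 to 0.542% in PBS and 0.34 to 0.393% in cisplatin libraries of the first batch.

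**Figure D1:**
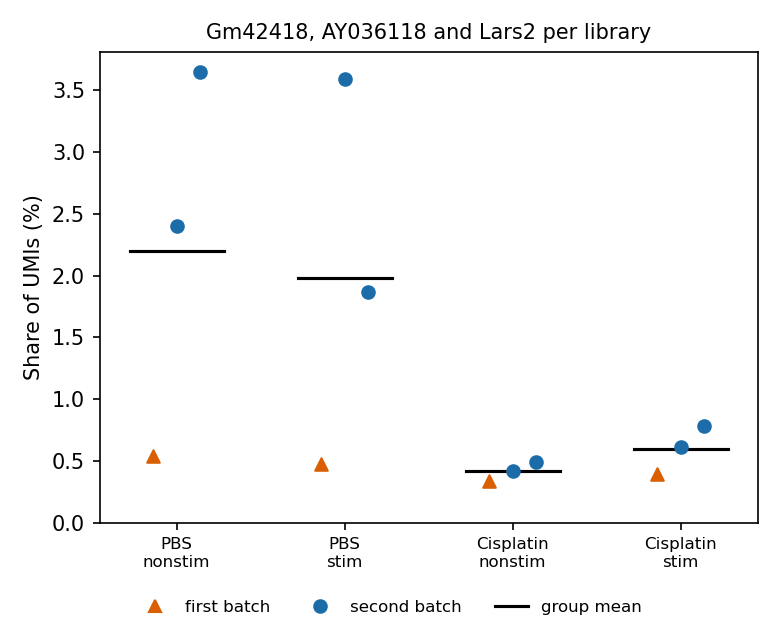
Share of UMIs (percent, vertical axis) taken by Gm42418, AY036118 and Lars2 together in each of the 12 libraries, with 1 column of points per group, colour and symbol for the batch and a line at the group mean. The 4 PBS libraries of the second batch lie between 1.87 and 3.65%, above every other library.

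Cisplatin nonstim was compared with PBS nonstim to ask what the drug changed in unstimulated mice. In oligodendrocytes, the myelinating cells, 336 genes rose and 295 fell among 10094 tested. Itgad, an integrin alpha subunit (chromosome 7, 128154376 to 128223816, GRCm38), stood at 14.3 ± 2.70 CPM (UMI counts scaled to a common library total; SD, n = 3) in PBS nonstim and 72.8 ± 22.8 in Cisplatin nonstim. Its log2 fold change was 2.42 ± 0.19 (SE), with edgeR adjusted p = 6.56e-07. Cxcl12, a chemokine (chromosome 6, 117168535 to 117181367), rose by 3.20 ± 0.31 on the log2 scale (edgeR adjusted p = 7.33e-06), from 4.40 ± 1.67 to 38.4 ± 15.5 CPM. Cxcl12 is also among the leading genes of endothelium here, and RNA from endothelium was not tested as its source in any comparison. Itih5, which binds hyaluronan in the matrix, rose by 2.54 ± 0.24 (edgeR adjusted p = 6.99e-06) and Plin4, a lipid droplet coat protein, by 1.96 ± 0.23 (edgeR adjusted p = 0.000131). All 3 Cisplatin nonstim libraries exceeded all 3 PBS nonstim libraries for each of these 4 genes.

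The genes that fell most clearly in oligodendrocytes were Poc1a, a centriole protein, by 1.18 ± 0.16 (edgeR adjusted p = 0.000245) and the sorting receptor Sort1, by 0.74 ± 0.10. The linker histone Hist1h1e and Itih3 fell as well, the latter by 0.90 ± 0.13. Hist1h1e shares a fraction of 0.617 of its 31-base words with other genes, so its level is uncertain. Of the 15 measured members of the glucocorticoid response list, 9 rose and 0 fell, and 9 and 0 did when adjusted over the list alone. The list passed upward (mean log2 fold change 1.17, camera (limma) adjusted p = 5.5e-08, adjusted p = 0.559 with an estimated correlation). They included Fkbp5, a co-chaperone of the glucocorticoid receptor (2.47 ± 0.33, edgeR adjusted p = 0.00025), the hypoxia-inducible factor Hif3a (3.25 ± 0.47, edgeR adjusted p = 0.000469) and Cdkn1a, the cyclin-dependent kinase inhibitor p21 and also a p53 target (3.45 ± 0.50, edgeR adjusted p = 0.000527). The immediate early and dissociation list had 9 of 26 members higher, 15 higher and 1 lower adjusted over the list alone (mean 0.56, camera adjusted p = 9.81e-05, adjusted p = 0.785 with an estimated correlation). Among them were the phosphatase Dusp1 (1.5 ± 0.27, edgeR adjusted p = 0.00268) and the nuclear receptor Nr4a1 (edgeR adjusted p = 0.00365). Circadian clock genes had 2 of 14 members higher, 4 higher and 1 lower adjusted over the list alone, with Per1 at 0.85 ± 0.18 (camera adjusted p = 0.00108, adjusted p = 0.618 with an estimated correlation). Members of the myelin list moved both ways. Apod, a lipid carrier, rose by 0.57 and the deacetylase Sirt2 by 0.48, while the small heat shock protein Cryab fell by 0.63 (edgeR adjusted p = 0.00309, 0.00533 and 0.00127). The p53 targets Bbc3 and Btg2 rose by 1.27 ± 0.24 and 0.97 (edgeR adjusted p = 0.00359 and 0.0346). Of 7 astrocyte markers 1 was called higher in oligodendrocytes, Aldoc at 0.66 (edgeR adjusted p = 0.01), and of 4 in OPCs 1 was, Aldoc again, at 1.28 (edgeR adjusted p = 2.06e-05).

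Microglia, the resident macrophages of the brain, had 219 genes higher and 137 lower among 9903. Lsp1, an actin-binding protein of leukocytes (chromosome 7, 142460809 to 142494867), rose by 1.37 ± 0.15 (edgeR adjusted p = 1.91e-05), from 45.4 ± 4.06 to 115 ± 38.6 CPM. The kinase gene Pim1 rose by 1.53 ± 0.20, the mTORC1 inhibitor Ddit4 by 1.79 and the cold-inducible RNA-binding protein Rbm3 by 1.07 ± 0.15 (edgeR adjusted p = 0.000143, 0.000367 and 0.000392). The histone H4 genes Hist1h4d and Hist1h4h fell by 1.90 ± 0.23 and 2.14 ± 0.27 (edgeR adjusted p = 7.05e-05 and 0.0001), and Hist1h1e fell as well. Hist1h4h shares a fraction of 0.493 of its 31-base words with other genes, just under the 0.5 that marks a near copy. Tlr3, a receptor for double-stranded RNA, fell by 0.73 ± 0.12 (edgeR adjusted p = 0.00125). Of the disease-associated microglia list, Apoe rose by 1.02 and the iron-storage gene Fth1 by 0.47, while galectin-3 (Lgals3) fell by 1.97 ± 0.37 (edgeR adjusted p = 0.00973, 0.0422 and 0.00379). The interferon response list had 3 of 24 members higher, 10 adjusted over the list alone (mean 0.68, camera adjusted p = 0.000376, adjusted p = 0.785 with an estimated correlation). Homeostatic microglia genes were lower as a list, with 1 of 19 members called both over all genes and adjusted over the list alone (mean −0.13, camera adjusted p = 0.0222, adjusted p = 0.785 with an estimated correlation). The p53 target Gdf15 fell by 1.13 ± 0.27 (edgeR adjusted p = 0.0208). Of 6 oligodendrocyte markers 2 were called higher in microglia, with Mobp at 0.716 (edgeR adjusted p = 0.0148).

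In the endothelium 45 genes rose and 32 fell among 8145. Igfbp3, which binds insulin-like growth factors, rose by 2.73 ± 0.34, von Willebrand factor (Vwf, a clotting protein) by 1.74 ± 0.21, and the protease inhibitor Serpine2 by 1.37 ± 0.18 (edgeR adjusted p = 0.000168, 0.000168 and 0.000171). Vwf stood at 132 ± 11.3 CPM in PBS nonstim and 444 ± 86.8 in Cisplatin nonstim (SD, n = 3). The p53 target list had 4 of 21 members higher, 10 higher and 1 lower adjusted over the list alone (mean 0.46, camera adjusted p = 1.05e-05, adjusted p = 0.12 with an estimated correlation). It was led by Phlda3, an Akt inhibitor (chromosome 1, 135766119 to 135769136), at 2.38 ± 0.31 (edgeR adjusted p = 0.000171). Trp53inp1 (1.24 ± 0.21) and cyclin G1 (Ccng1, 1.11 ± 0.26, edgeR adjusted p = 0.0352) rose too. In pericytes the same list had 1 of 21 members higher, 4 adjusted over the list alone (camera adjusted p = 8.41e-05, adjusted p = 0.437 with an estimated correlation). Phlda3 rose there by 2.44 ± 0.52 (edgeR adjusted p = 0.0378), and the apoptosis gene Bax was at 0.84 without a call (edgeR adjusted p = 0.298). Endothelial activation genes had 2 of 8 members higher, 4 adjusted over the list alone (mean 1.14, camera adjusted p = 5.9e-05, adjusted p = 0.618 with an estimated correlation), among them the adhesion molecule Icam1 (1.30 ± 0.28). Icam1 was also the member called in the inflammatory cytokine and NF-kB list, 1 of 9 over all genes and adjusted over the list alone (camera adjusted p = 0.0425, adjusted p = 0.785 with an estimated correlation), and its mean was −0.234 with the share of ribosomal RNA-like transcripts as a covariate.

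Endothelial genes that fell included the metalloprotease Adamts1 by 1.12 ± 0.18, the chromatin remodeller Smarca2 by 0.82 ± 0.14, AY036118 by 3.17 ± 0.51 and Lars2 by 1.91 ± 0.32 (edgeR adjusted p = 0.00188, 0.0024, 0.00188 and 0.0024). Interferon response genes were lower, 2 of 26 over all genes and 11 adjusted over the list alone (mean −0.43, camera adjusted p = 5.11e-08, adjusted p = 0.618 with an estimated correlation). Ifi27l2a was at −2.35 ± 0.44 and Slfn2 at −1.28. MHC class I presentation genes were lower, 2 of 13 over all genes and 8 adjusted over the list alone (mean −0.48, camera adjusted p = 7.7e-08, adjusted p = 0.559 with an estimated correlation). The immunoproteasome subunit Psmb9 was at −0.67 ± 0.15 and B2m, the light chain of class I molecules, at −0.66 ± 0.15. The interferon list thus passed with opposite signs in microglia and endothelium, a difference that was not itself tested.

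In astrocytes 22 genes rose and 15 fell among 10163. Angiotensinogen (Agt) rose by 0.94 ± 0.13 and Etnppl, a lyase of phosphoethanolamine, by 1.38 ± 0.19 (edgeR adjusted p = 0.000319 for each), and all 3 Cisplatin nonstim libraries exceeded all 3 PBS nonstim libraries for Agt. Ttr, transthyretin, a choroid plexus marker, was higher by 3.93 ± 0.53 (edgeR adjusted p = 0.000319), and Mobp, an oligodendrocyte marker, by 0.835 (edgeR adjusted p = 0.0271). Rbm3 rose by 0.99 ± 0.16 (edgeR adjusted p = 0.00222). Lars2 fell by 2.04 ± 0.32, the thioesterase gene Them4 by 0.96 ± 0.17, Hist1h1e by 1.55 ± 0.28 and the fatty acid-binding protein Fabp7 by 1.10 ± 0.20 (edgeR adjusted p = 0.00171, 0.00607, 0.00704 and 0.00829). Cholesterol synthesis genes were lower, 2 of 24 over all genes and 5 adjusted over the list alone (mean −0.40, camera adjusted p = 8.22e-08, adjusted p = 0.785 with an estimated correlation). Hmgcs1 was at −0.78 ± 0.15 and Idi1 at −0.76. Of the reactive astrocyte list, Fkbp5 rose by 2.20 ± 0.49 (edgeR adjusted p = 0.0355) and the intermediate filament gene Vim was at 0.70 ± 0.21 without a call (edgeR adjusted p = 0.176). In neurons the synaptic vesicle list passed upward (mean 0.25, 0 of 21 members called, 3 adjusted over the list alone; camera adjusted p = 0.0159, adjusted p = 0.785 with an estimated correlation). The authors' neuron cluster 10, with a median of 31.8% mitochondrial UMIs per cell, held 28.8% of neurons in PBS nonstim and 52.1% in Cisplatin nonstim, and cluster 12, led by Meg3 and Grin2a, 52.0 and 38.7%. In OPCs the cell cycle list passed downward (mean −0.71, 0 of 17 called, 9 adjusted over the list alone; camera adjusted p = 0.0463, adjusted p = 0.837 with an estimated correlation). Its mean was 0.042 without PBS nonstim 3 and 0.576 with the covariate. The shallow OPC cluster 18 (median 1656 UMIs) held 26.5% of OPCs in PBS nonstim and 31% in Cisplatin nonstim in the first batch, 11.2 and 6.41% in the second, and cluster 9 the rest.

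Over 9 cell types this comparison gave 1142 calls in 69488 tests, 651 higher and 491 lower (edgeR quasi-likelihood test, Benjamini-Hochberg within a cell type). OPCs had 23 of them, pericytes 16 and immune cells and neurons 1 each. Neuron calls numbered 175 without Cisplatin nonstim 1, 40 without PBS stim 1, 32 without Cisplatin stim 2, 65 by DESeq2 and 227 in the second batch alone. With 1 library left out at a time, OPC calls ran from 8 without Cisplatin nonstim 2 to 37 without Cisplatin nonstim 1, and pericyte calls from 10 without PBS nonstim 2 or Cisplatin nonstim 3 to 30 without PBS nonstim 1. Oligodendrocyte calls ran from 123 and microglial calls from 54 without Cisplatin nonstim 2 to 1011 and 631 without Cisplatin nonstim 1. Endothelial calls ran from 24 without PBS nonstim 3 to 137 without PBS nonstim 1, and those of astrocytes from 7 without Cisplatin nonstim 3 to 83 without Cisplatin stim 1. Choroid plexus had 0 calls by edgeR, with 1846 genes at an unadjusted p under 0.05, 122 calls by DESeq2 and 18 by limma-voom. Choroid plexus calls numbered 1674 without PBS nonstim 1, 354 without PBS stim 1, 292 without Cisplatin nonstim 1, 18 without Cisplatin stim 1 and 3198 in the second batch alone. Of 117 list tests 34 passed, 0 with an estimated correlation. Of the 58 calls named here 36 held whichever library was left out. The count of gene calls fell to 236 without Cisplatin nonstim 2, 334 without PBS nonstim 3, 404 without Cisplatin nonstim 3 and 448 without PBS nonstim 2. It was 3223 without PBS nonstim 1 and 2366 without Cisplatin nonstim 1. It was 25 with the share of the ribosomal RNA-like transcripts as a covariate, 142 without the PBS libraries of the second batch and 6895 in the second batch alone. The first batch holds 1 library per group and gives no test.

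Stimulation in cisplatin mice was tested by comparing Cisplatin stim with Cisplatin nonstim. Oligodendrocytes again had the most calls, with 73 genes higher and 27 lower. Cdkn1a (chromosome 17, 29090976 to 29100727) rose by a further 3.44 ± 0.32 on the log2 scale (edgeR adjusted p = 1.06e-05). It stood at 37.3 ± 18.8 CPM in Cisplatin nonstim and 489 ± 410 in Cisplatin stim, against 3.20 ± 3.02 in PBS nonstim and 2.53 ± 1.39 in PBS stim (SD, n = 3). The tetraspanin Tspan4 rose by 3.86 ± 0.43 (edgeR adjusted p = 8.01e-05), with 154 CPM in Cisplatin stim 1 and 14.8 and 18.6 in the other Cisplatin stim libraries. Plin4 rose by 1.65 ± 0.18 and Cxcl12 by 1.77 ± 0.21 (edgeR adjusted p = 8.01e-05 and 0.000196). For these 4 genes all 3 Cisplatin stim libraries exceeded all 3 Cisplatin nonstim libraries, as the plot of oligodendrocyte levels shows for Cdkn1a and Plin4.

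**Figure D2:**
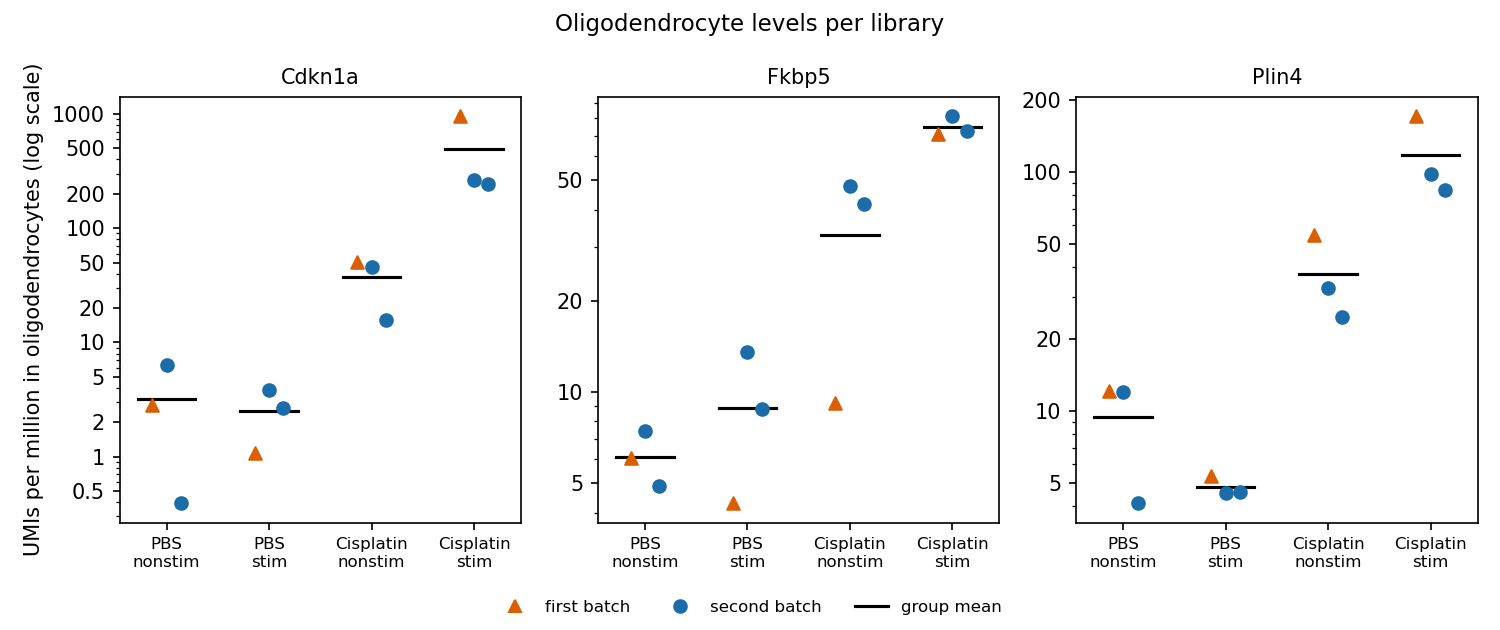
CPM (log axis) of Cdkn1a, Fkbp5 and Plin4 in oligodendrocytes of each library, with 1 column of points per group, colour and symbol for the batch and a line at the group mean. Cdkn1a lies between 242 and 962 in Cisplatin stim, between 15.7 and 50.4 in Cisplatin nonstim and at or below 6.4 in the PBS libraries.

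The glucocorticoid response list had 10 of 15 members higher in oligodendrocytes, 11 adjusted over the list alone (mean 1.19, camera adjusted p = 7.02e-11, adjusted p = 0.439 with an estimated correlation). Beside Cdkn1a and Plin4 these included Fkbp5 (1.25 ± 0.25, edgeR adjusted p = 0.0164), the sulfotransferase Sult1a1 (1.84 ± 0.31, edgeR adjusted p = 0.00434) and the metallothionein Mt2 (1.79 ± 0.31, edgeR adjusted p = 0.00534). The list was also higher in endothelium (mean 0.72; 0 of 15 members called, 7 adjusted over the list alone; camera adjusted p = 1.76e-07, adjusted p = 0.69 with an estimated correlation). In pericytes it had 0 of 13 members called and 5 adjusted over the list alone (mean 0.65, camera adjusted p = 5.18e-07, adjusted p = 0.439 with an estimated correlation). In astrocytes 1 of 15 was called and 9 adjusted over the list alone (mean 0.55, camera adjusted p = 1.32e-05, adjusted p = 0.69 with an estimated correlation). The called member was Fkbp5 at 1.95 ± 0.32 (edgeR adjusted p = 0.00744).

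Oligodendrocyte genes that fell with stimulation included Shtn1, a regulator of neuronal polarity, by 0.88 ± 0.15, the Hsp90 co-chaperone Chordc1 by 0.80 ± 0.14, the long noncoding RNA Sox2ot by 0.66 ± 0.12 and Adamtsl1 by 0.80 ± 0.15 (edgeR adjusted p = 0.00434, 0.00682, 0.00971 and 0.0101). The myelin list was lower (mean −0.16; 1 of 27 members higher and 2 lower, 1 and 9 adjusted over the list alone; camera adjusted p = 0.0125, adjusted p = 0.811 with an estimated correlation). Its called members were Ugt8a, the synthase of galactosylceramide, at −0.77 ± 0.16, Cryab at −0.49 ± 0.10 and, upward, Apod at 0.67 (edgeR adjusted p = 0.0161, 0.0194 and 0.00241). Cholesterol synthesis genes were lower in these cells (mean −0.29; 1 of 24 called, 6 adjusted over the list alone; camera adjusted p = 0.000266, adjusted p = 0.69 with an estimated correlation). So were immediate early genes (mean −0.42; 0 of 26 called and 0 adjusted over the list alone; camera adjusted p = 0.000228, adjusted p = 0.744 with an estimated correlation).

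Endothelial calls with stimulation included Ccn2, a matricellular growth factor (1.73 ± 0.31), and Trp53inp1 (0.95 ± 0.17), each at edgeR adjusted p = 0.0282. Ccn2 stood at 440 ± 138 CPM in Cisplatin stim and 137 ± 82.7 in Cisplatin nonstim. Eno1b, which shares a fraction of 0.875 of its 31-base words with other genes, was at 2.36 ± 0.43, Wdr89 at 1.54 ± 0.29 (edgeR adjusted p = 0.0373) and the glutathione transferase Gstp1 at −1.69 ± 0.31. Interferon genes were lower in endothelium (mean −0.33; 0 of 26 called, 1 adjusted over the list alone; camera adjusted p = 4.22e-05, adjusted p = 0.69 with an estimated correlation). In microglia Ddit4 rose by 1.60 ± 0.21 (edgeR adjusted p = 0.000521) and the chemokine Cxcl2 by 1.00 ± 0.18 (edgeR adjusted p = 0.0182), while the transcription factor Klf2 fell by 0.82 ± 0.16 (edgeR adjusted p = 0.0341). Eno1b, Gstp1, the pseudogene Rpl10-ps3 and Hist1h2ap were also called there at 2.25 ± 0.40, −1.82 ± 0.32, 1.99 ± 0.33 and −1.91 ± 0.38. All but Gstp1, at 0.422, share a fraction of at least 0.875 of their 31-base words. Hist1h2ap was not called with the replicate number as a block (edgeR adjusted p = 0.0623). Over all cells of a library Eno1b was at 94.9 and 133 CPM in Cisplatin stim 2 and 3, 23.7 and 20.9 in Cisplatin nonstim 2 and 3, 7.78 in Cisplatin stim 1 and 7.16 in Cisplatin nonstim 1. Gstp1 was at 91.4, 67.2, 193, 254, 272 and 271 CPM in the same 6 libraries in that order. In microglia Cisplatin stim 1 and Cisplatin nonstim 1 had 11.4 and 3.58 CPM of Eno1b and 15.2 and 47 of Gstp1. Without Cisplatin stim 2 and 3 none of these 4 was called in microglia (Eno1b 1.32, Gstp1 −1.84, Rpl10-ps3 0.21, Hist1h2ap −2.19), nor were Eno1b (1.14), Wdr89 (1.39) and Gstp1 (−1.82) in endothelium. Disease-associated microglia genes passed upward (mean 0.24; 0 of 24 called over all genes or adjusted over the list alone; camera adjusted p = 0.0358, adjusted p = 0.876 with an estimated correlation), with a mean of −0.107 without Cisplatin stim 1 and −0.002 in the second batch alone. Homeostatic microglia genes passed downward (mean −0.19; 0 of 19 called, 2 adjusted over the list alone; camera adjusted p = 0.00207, adjusted p = 0.69 with an estimated correlation).

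All 4 calls in OPCs were Cdkn1a (2.43 ± 0.49, edgeR adjusted p = 0.0351), the sulfotransferase Chst2 (0.95 ± 0.16), the noncoding RNA Bc1 (1.09 ± 0.21, edgeR adjusted p = 0.0222) and prostaglandin D synthase (Ptgds, −1.25 ± 0.22, edgeR adjusted p = 0.00544). MHC class II genes in immune cells passed upward with stimulation (mean 1.06; 0 of 6 called over all genes or adjusted over the list alone; camera adjusted p = 0.000273, adjusted p = 0.69 with an estimated correlation). Immune cluster 15, whose leading genes include Cd74, H2-Eb1 and H2-Aa, held 25.9% of immune cells in Cisplatin nonstim and 20.6% in Cisplatin stim in the first batch, and 47.0 and 62.3% in the second, where Cisplatin stim 2 had 16 cells of it and 1 of cluster 14. Synaptic vesicle genes in neurons passed downward (mean −0.28; 0 of 21 called over all genes or adjusted over the list alone; camera adjusted p = 0.0275, adjusted p = 0.69 with an estimated correlation). Neuron cluster 10 held 52.1% of neurons in Cisplatin nonstim and 74.8% in Cisplatin stim, and cluster 12 38.7 and 20.9%. The comparison made 136 calls, 101 higher and 35 lower, and 40 of 117 list tests passed, 0 with an estimated correlation. Oligodendrocyte calls numbered 29 without Cisplatin nonstim 1, 35 without Cisplatin nonstim 3 and 44 without Cisplatin stim 1. All calls numbered 49 without Cisplatin nonstim 1, 61 without Cisplatin nonstim 3 and 80 without Cisplatin stim 1, and 15 with no batch term.

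Stimulation in PBS mice, PBS stim against PBS nonstim, gave 0 calls by edgeR, with 1992 of 69488 tests at an unadjusted p under 0.05, 7 calls by DESeq2 and 0 by limma-voom. The endothelial p53 target Trp53inp1 was at 0.71 ± 0.25 and Lgals3 in microglia at −0.94 ± 0.31, neither of them called (edgeR adjusted p = 1 for each). At the list level, immediate early genes were higher in oligodendrocytes (mean 0.32, 23 of 26 positive, 0 called over all genes or adjusted over the list alone; camera adjusted p = 0.0195, adjusted p = 0.984 with an estimated correlation). MHC class I genes were higher there too (mean 0.54; 0 of 8 called, 3 adjusted over the list alone; camera adjusted p = 0.0228, adjusted p = 0.984 with an estimated correlation). Oxidative phosphorylation genes were lower in astrocytes (mean −0.10; 0 of 61 called over all genes or adjusted over the list alone; camera adjusted p = 0.00982, adjusted p = 0.984 with an estimated correlation). Mitochondrially encoded genes were lower in choroid plexus (mean −0.96; 0 of 13 called over all genes or adjusted over the list alone; camera adjusted p = 0.0228, adjusted p = 0.984 with an estimated correlation). In all 9 of 117 list tests passed, 0 with an estimated correlation. They numbered 26 without PBS nonstim 1, 25 without PBS stim 1, 16 without Cisplatin stim 1, 15 without Cisplatin nonstim 1 or Cisplatin stim 3 and 14 without Cisplatin nonstim 2. Removing any 1 library gave 1 to 13 gene calls, with 13 without PBS stim 1, 6 without PBS nonstim 3 and 4 without PBS nonstim 2 or Cisplatin nonstim 3.

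Whether stimulation acted differently in cisplatin and PBS mice was tested as the interaction, the stimulation effect in cisplatin mice minus that in PBS mice. Plin4 in oligodendrocytes had an interaction of 2.50 ± 0.40 (edgeR adjusted p = 0.0138), from a stimulation effect of 1.65 in cisplatin and −0.85 in PBS mice. Apod had one of 0.83 ± 0.15 (edgeR adjusted p = 0.0246). Scrg1 was at 2.15 ± 0.40, Usp50 at 2.21 ± 0.35 and Nkain1, which interacts with the sodium pump, at −1.16 ± 0.21 in the same cells (edgeR adjusted p = 0.0365, 0.0138 and 0.0316). Nrarp, a target and inhibitor of Notch signalling, was at 2.39 ± 0.44 in pericytes (edgeR adjusted p = 0.0453). The choroid plexus marker Ttr was at −4.01 ± 0.70 in astrocytes, −5.38 ± 0.92 in OPCs and −4.78 ± 0.55 in pericytes (edgeR adjusted p = 0.0378, 0.00781 and 5.57e-05), and the call in astrocytes was lost with the replicate number as a block (edgeR adjusted p = 0.205). Gm2000 (2.33 ± 0.30 in microglia, 2.17 ± 0.35 in oligodendrocytes), Gm11808 (1.39 ± 0.23), Rpl10-ps3 (2.72 ± 0.47) and Rps27rt in neurons (3.20 ± 0.55) were called as well. They share fractions of 0.904, 0.947, 0.945 and 0.924 of their 31-base words with other genes, so their counts are uncertain. Gstp1 was at −2.45 ± 0.40 in microglia and −1.66 ± 0.28 in oligodendrocytes. Without Cisplatin stim 2 and 3, whose levels of Gstp1 over all cells were the lowest of the 12 libraries, it was at −2.47 in microglia without a call (edgeR adjusted p = 0.159) and at −1.17 in oligodendrocytes (edgeR adjusted p = 0.0372).

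These are 16 of the 17 calls of the interaction, which fell in 13 genes. The glucocorticoid response list had a positive interaction in oligodendrocytes (mean 1.24; 1 of 15 called, 6 adjusted over the list alone; camera adjusted p = 6.34e-08). The immediate early list had a negative one there (mean −0.74; 0 of 26 called, 4 lower adjusted over the list alone; camera adjusted p = 3.72e-06). Ribosomal protein genes in neurons had a positive one (mean 0.45, 0 of 77 called, camera adjusted p = 7.07e-10). So did mitochondrially encoded genes in choroid plexus (mean 1.36, 0 of 13 called, camera adjusted p = 0.0024). In both 0 were called adjusted over the list alone. Each of these lists had adjusted p = 0.954 with an estimated correlation. The choroid plexus cluster mix given above was not tested as a source. Neuron cluster 10 held 32.6, 68.1, 50.5 and 78.1% of neurons in PBS nonstim, PBS stim, Cisplatin nonstim and Cisplatin stim of the first batch and 27.5, 25.3, 53.3 and 67.8% in the second. In all 32 of 117 list tests passed, 0 with an estimated correlation, with 14 without Cisplatin stim 1 and 21 without PBS nonstim 2. Calls numbered 3 without PBS stim 3, 9 without Cisplatin nonstim 2, 26 without PBS stim 1, 40 without Cisplatin stim 1 and 41 without PBS nonstim 3. Of the 16 calls named here Gm2000 in microglia was the 1 kept in every such fit. Without both Cisplatin stim 2 and 3, however, it was at 0.965 in place of 2.33, Gm2000 in oligodendrocytes at 1.33 and Rpl10-ps3 in microglia at 0.91.

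To see whether stimulation moved genes back towards PBS levels, the log2 fold changes of cisplatin in unstimulated mice were set against those of stimulation in cisplatin mice. Both use the Cisplatin nonstim libraries with opposite signs, so unchanged groups already give a negative correlation across genes, with a median of −0.484 in 100 simulations. The observed median over 9 cell types was −0.168, from −0.402 in OPCs to 0.063 in oligodendrocytes, and it was −0.451 without Cisplatin nonstim 1 and −0.326 without Cisplatin nonstim 2. In oligodendrocytes the covariance was 0.0084 against a simulated mean of −0.0296. It lay above all simulations in 7 types and below all of them in 2, choroid plexus and OPCs. The simulations draw all libraries independently, whereas same-numbered libraries of the cisplatin arm deviate together, which by itself makes these values less negative, so the distance from the simulations does not measure a shared effect. Of the 631 genes called with cisplatin in oligodendrocytes, 403 (63.9%) had the same sign with stimulation, against 46.1% of 356 in microglia, 51.9% of 77 in endothelium, 51.4% of 37 in astrocytes, 56.5% of 23 in OPCs and 37.5% of 16 in pericytes. In both comparisons 43 were called in oligodendrocytes, 40 in the same direction, where independent lists would share 6.25. The 3 shared libraries could not be divided, and their chance values enter with opposite signs, so they add overlaps in opposite directions, of which there were 3.

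Cisplatin was also averaged over stimulation, both cisplatin groups against both PBS groups, to describe the drug effect with 6 libraries on each side. In oligodendrocytes 1138 genes rose and 1216 fell, led by Itgad (2.93 ± 0.14, edgeR adjusted p = 6.2e-11), Cxcl12 (4.07 ± 0.23), Itih5 and Plin4 (3.21 ± 0.18; edgeR adjusted p = 4.26e-10 for the last 3). Cdkn1a rose by 5.19 ± 0.35 and Fkbp5 by 2.76 ± 0.23 (edgeR adjusted p = 6.43e-09 and 7.94e-08), and all 6 cisplatin libraries exceeded all 6 PBS libraries for Cdkn1a. Cdkn1a was at 7.71 ± 1.53 within the first batch and 5.33 ± 0.75 within the second, and Fkbp5 at 2.80 ± 0.91 and 2.87 ± 0.24. Bbc3 rose by 1.43, Apod by 0.99 and the myelin protein gene Mobp by 0.66, while Itih3 fell by 1.41 ± 0.10, Shtn1 by 1.20 ± 0.10, Sort1 by 0.86 ± 0.07 and Cryab by 0.87 ± 0.07. Markers of other cells were called higher in oligodendrocytes as well: 3 of 6 erythrocyte markers (median 1.64), 1 of 7 astrocyte markers (Aldoc 0.92, with 1 lower) and 2 of 4 excitatory neuron markers (median 0.613, with 1 lower). The glucocorticoid response list had 12 of 15 members higher, also 12 adjusted over the list alone (mean 1.79, camera adjusted p = 5.88e-10, adjusted p = 0.389 with an estimated correlation, fry adjusted p = 0.000896).

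In microglia 812 genes rose and 654 fell. With 1 library left out at a time microglial calls ran from 836 without Cisplatin stim 2 to 1698 without Cisplatin nonstim 1, and they numbered 12 with the covariate. Lsp1 rose by 1.45 ± 0.11, Ddit4 by 2.10 ± 0.17, the transcription factor Jdp2 by 1.67 ± 0.15 and Sult1a1 by 1.15 ± 0.10 (edgeR adjusted p = 3.47e-08, 4.72e-08, 2.17e-07 and 2.17e-07). Hist1h4h fell by 2.17 ± 0.21, Hist1h4d by 1.76 ± 0.17, Lst1 by 1.18 and the microglial Fc receptor-like gene Fcrls by 0.89 ± 0.08 (edgeR adjusted p = 5.15e-07, 5.3e-07, 5.73e-07 and 2.17e-07). Hist1h4h, with its shared fraction of 0.493, was at 0.483 without the PBS libraries of the second batch. Apoe rose by 1.22 and Fth1 by 0.53, while Lgals3 fell by 1.84 ± 0.32. Markers of other cells moved with these groups: 2 of 6 oligodendrocyte markers were called higher in microglia (median 0.383, Mobp 0.825) and 1 of 6 astrocyte markers (Aldoc, 0.897), while 2 of 7 microglia markers were lower (Cx3cr1 −0.291). Homeostatic microglia genes had 10 of 19 members lower, 10 adjusted over the list alone (mean −0.24, camera adjusted p = 9.17e-05, adjusted p = 0.459 with an estimated correlation). Ribosomal protein genes had 55 of 77 higher and 1 lower, 65 and 1 adjusted over the list alone (mean 0.30, camera adjusted p = 1.18e-22, adjusted p = 0.486 with an estimated correlation). The complement and synapse pruning list did not pass in any comparison (here mean 0.05, median −0.03, 1 of 10 called over all genes and adjusted over the list alone, camera adjusted p = 0.968).

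Endothelial p53 targets had 9 of 21 members higher, 10 higher and 1 lower adjusted over the list alone (mean 0.47, camera adjusted p = 6.02e-05, adjusted p = 0.201 with an estimated correlation, fry adjusted p = 0.000711). Phlda3 rose by 2.67 and Trp53inp1 by 1.36, and Phlda3 was at 1.82 ± 0.71 within the first batch and 2.69 ± 0.22 within the second. In pericytes the list had 3 of 21 higher, 12 higher and 1 lower adjusted over the list alone, with Phlda3 at 3.1 (camera adjusted p = 1.84e-05, adjusted p = 0.313 with an estimated correlation). Endothelial activation genes had 5 of 8 members higher, 6 adjusted over the list alone (mean 1.33, camera adjusted p = 5.99e-06, adjusted p = 0.389 with an estimated correlation). Interferon genes had 11 of 26 lower, 17 adjusted over the list alone (mean −0.48, camera adjusted p = 2e-09, adjusted p = 0.389 with an estimated correlation). The blood-brain barrier list did not pass in any comparison (here mean 0.02, median −0.03 and a downward test; 3 of 20 higher and 2 lower, 5 and 4 adjusted over the list alone; camera adjusted p = 0.937).

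In astrocytes Fkbp5 rose by 3.38, Cdkn1a by 3.13, the elastic fibre protein Fbln5 by 1.52 and Vim by 0.65. Markers of other cells were called higher there too: 2 of 7 oligodendrocyte markers (Mobp 0.678), 1 of 6 excitatory neuron markers (Slc17a7 0.966) and 1 of 5 erythrocyte markers (Hba-a2 2.83). The reactive astrocyte list had 4 of 12 members higher, 5 adjusted over the list alone (mean 0.47, camera adjusted p = 0.0125, adjusted p = 0.459 with an estimated correlation). Cholesterol synthesis genes had 8 of 24 members lower, 16 adjusted over the list alone (mean −0.42, camera adjusted p = 5.93e-09, adjusted p = 0.477 with an estimated correlation). The integrated stress and unfolded protein response list was lower (mean −0.19; 5 of 21 lower, 7 lower and 1 higher adjusted over the list alone; camera adjusted p = 0.0158, adjusted p = 0.686 with an estimated correlation). Homeostatic astrocyte genes did not pass in any comparison (here mean −0.06; 2 of 16 higher and 1 lower, 2 and 3 adjusted over the list alone; camera adjusted p = 0.339). In OPCs the cell cycle list was lower (mean −0.76; 0 of 17 called, 1 adjusted over the list alone; camera adjusted p = 0.00305, adjusted p = 0.686 with an estimated correlation), with a mean of 0.316 with the covariate. OPC cluster 18 held 16.1% of OPCs in PBS and 7.09% in cisplatin libraries of the second batch, 26.0 and 27.3% in the first, and cluster 9 the rest. The astrocyte marker Aldoc was higher in OPCs by 1.44 (edgeR adjusted p = 1e-09). The OPC differentiation list passed in no comparison (here mean 0.07; 2 of 16 higher, 3 higher and 1 lower adjusted over the list alone; camera adjusted p = 0.339).

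Neurons had 439 genes higher and 111 lower. With 1 library left out at a time neuron calls ran from 246 without PBS stim 2 to 817 without PBS stim 1, and they numbered 0 with the covariate. The cells came from different clusters: cluster 10 held 32.7% of neurons in PBS and 64.4% in cisplatin libraries, cluster 12 48.9 and 29.0%, and cluster 19 18.4 and 6.54%. The leading ones were Ptgds (1.92 ± 0.22, edgeR adjusted p = 3.79e-05), Ttr (a choroid plexus marker), Fam107a (2.40 ± 0.32) and Mt2 (1.45 ± 0.20). Those that fell were led by AY036118 (−2.21 ± 0.38, but 0.05 with the covariate, which includes this gene and so removes its change), Hist1h1e (−2.55 ± 0.44), gastrin-releasing peptide (Grp, −2.17 ± 0.39) and the cation channel Trpc6 (−1.31 ± 0.24). Markers of other cells moved with them: all 3 tested oligodendrocyte markers rose in neurons (median 1.82, Mobp 1.94) and 5 of 7 astrocyte markers did (median 1.44, Slc1a3 1.37). Ribosomal protein genes had 65 of 77 members higher in neurons, 73 adjusted over the list alone (mean 0.85, camera adjusted p = 1.23e-40, adjusted p = 0.399 with an estimated correlation). Oxidative phosphorylation genes had 32 of 61 higher, 49 adjusted over the list alone (mean 0.73, camera adjusted p = 2.02e-25, adjusted p = 0.421 with an estimated correlation). Of the neurons 73.3% exceeded 10% mitochondrial UMIs, and without such cells 6 libraries kept enough neurons, too few for a test. In choroid plexus Defb9 (1.76 ± 0.25), Rbm3 (1.64 ± 0.24), Cirbp (1.33 ± 0.19) and the chloride channel gene Clic3 (1.28 ± 0.18) rose. The kinase Map3k5 (−1.43 ± 0.20), Usp32 (−1.33 ± 0.19), the dynein Dnah6 (−1.85 ± 0.22) and Slc35f1 (−2.79 ± 0.41) fell. Each of these 8 had edgeR adjusted p = 0.00278 except Dnah6, at 0.0018. Of 6 oligodendrocyte markers 2 were called higher in choroid plexus (Mbp 1.0), and Aldoc was at 1.3 there.

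**Figure D3:**
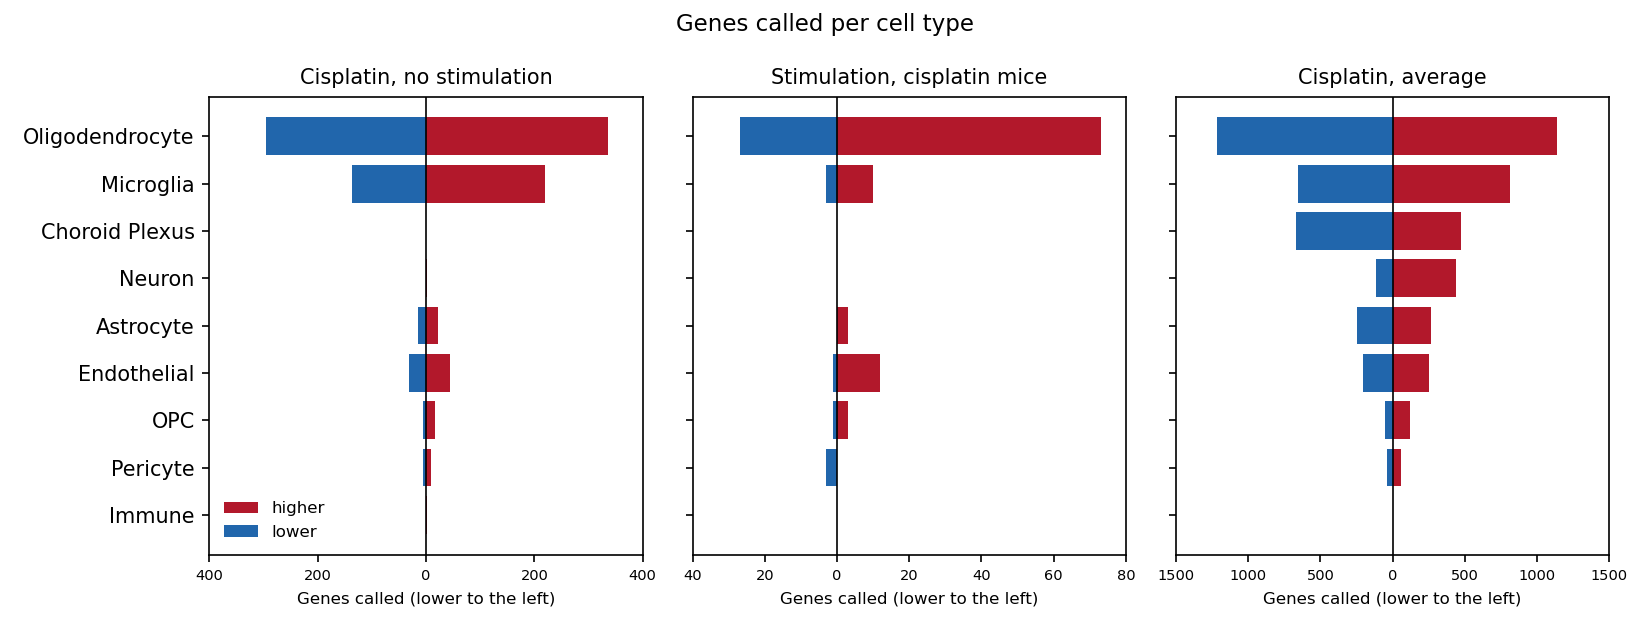
Number of genes (horizontal axis) called higher, to the right, and lower, to the left, at edgeR adjusted p under 0.05 per cell type in 3 comparisons. Oligodendrocytes have the most calls for cisplatin without stimulation (631), stimulation in cisplatin mice (100) and cisplatin averaged over stimulation (2354).

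Averaged over stimulation, cisplatin gave 6757 calls, 3560 higher and 3197 lower, and 43 of 117 list tests passed, 0 with an estimated correlation and 21 by fry. Fitted alone with its 4 groups, the second batch gave 12467 calls over 9 types. In fits of cisplatin against PBS over the 8 types with values in both batches, the second gave 11681 and the first 460, of which 387 lay in choroid plexus. The count was 3732 without Cisplatin nonstim 2, 3931 without PBS stim 3, 3984 without PBS stim 2, 4026 without Cisplatin stim 2, 4141 without PBS nonstim 3 and 4501 without Cisplatin nonstim 3. Of the genes called in the second batch in the 7 other types with values in both batches, pericytes having none in the first, 72.1% had the same sign in the first, where the other 2 splits of the 4 first-batch libraries gave 62.7 and 35%. The share was 26.4% of 4265 in the choroid plexus (60.8 and 42% in the other splits), where the PBS libraries of the first batch held 29 and 18 cells. The sides of the other splits are arbitrary, and exchanging them puts the 35% near the 62.7%. The 72.1% thus lies less far from them than it looks. With the share of the ribosomal RNA-like transcripts as a covariate 254 calls were made, 214 of them among the 6757, and 702 of the 6757 changed sign. In the second batch that share separates PBS from cisplatin libraries, so this fit has little power there. Without the 4 PBS libraries of the second batch, which leaves only the first batch in both PBS groups, 878 of the 6757 changed sign.

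The shares of cell types were compared to ask which populations changed in number. Progenitors made up 0.357 ± 0.187% of cells in the 6 cisplatin libraries and 1.494 ± 0.242% in the 6 PBS libraries (SD), a log2 difference of −2.09 (edgeR adjusted p = 0.000481). Microglia were at 17.7 ± 3.70% against 25.4 ± 3.89% (−0.53 ± 0.15, edgeR adjusted p = 0.0161) and choroid plexus cells at 19.5 ± 12.01% against 10.0 ± 8.63% (1.24 ± 0.34, edgeR adjusted p = 0.0161). The difference in progenitors was −1.66 within the first batch and −2.32 within the second, that in microglia −0.54 within each, and that in choroid plexus 1.81 and 0.93. In an exact two-sided permutation test within batches over 420 splits, progenitors and microglia reached the smallest possible p of 0.00476 (adjusted 0.0262), choroid plexus 0.0333 and OPCs 0.0286 (both adjusted 0.0916). These splits treat all libraries as independent. Same-numbered libraries of an arm kept together leave 12 splits within batches and a smallest p of 0.167, but such pairing was not measured for shares. Without Cisplatin stim 2 edgeR called 1 share in place of 3.

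In unstimulated mice progenitors were lower with cisplatin (−1.97 ± 0.42, edgeR adjusted p = 0.00711) and choroid plexus cells higher (1.94 ± 0.49, edgeR adjusted p = 0.0114), and 0 types were called without Cisplatin nonstim 2 and 1 without PBS nonstim 2. Stimulation changed 0 of 11 shares by edgeR in cisplatin mice and 0 in PBS mice, and the interaction 0, with 0, 1 and 0 types at an unadjusted p under 0.05. Shares sum to 1 and depend on dissection and dissociation, so a lower share of one type can follow from a higher share of another.

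**Figure D4:**
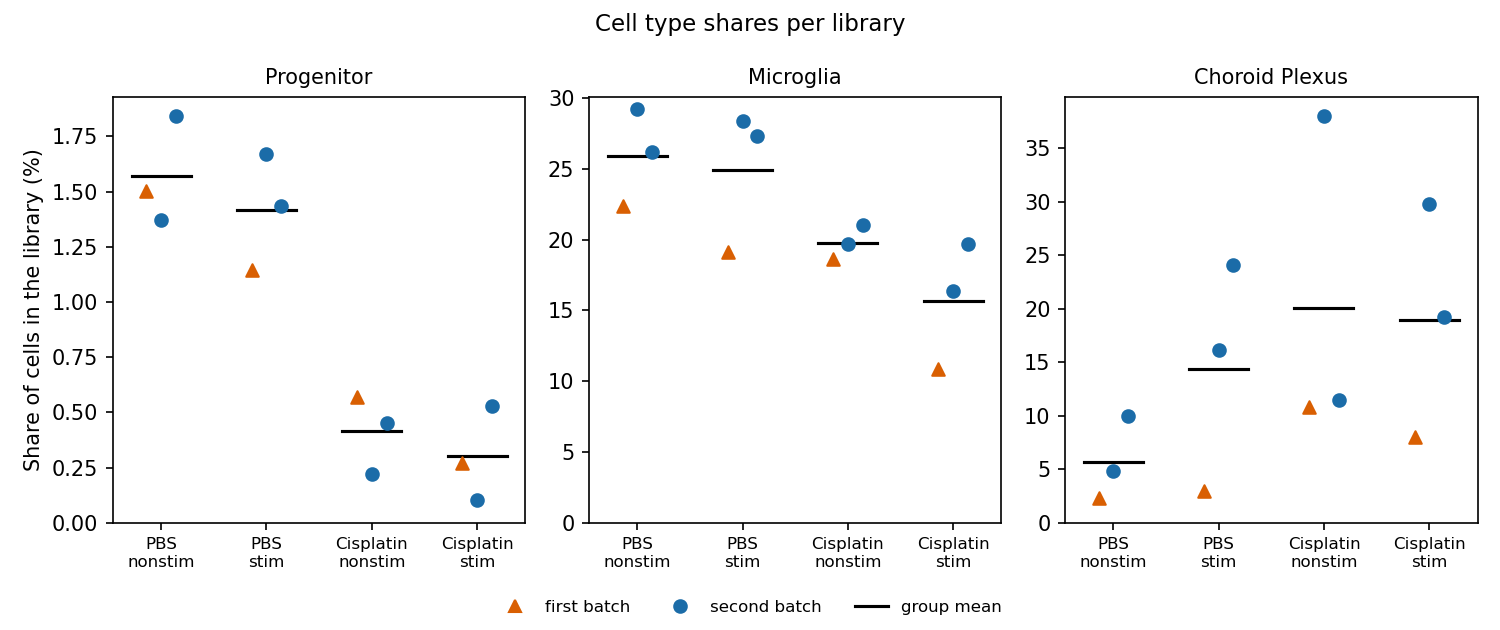
Share of cells (percent, vertical axis from 0) of progenitors, microglia and choroid plexus cells in each library, with 1 column of points per group, colour and symbol for the batch and a line at the group mean. Progenitors average 0.357% in cisplatin and 1.494% in PBS libraries, with no overlap between them.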

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

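The tests of the Ttr calls against RNA from choroid plexus cells, of RNA from other cell types as a whole and of doublets had their bounds written before their results were seen. The other tests in this part, all counts over other splits of the libraries included, were chosen only after the results were seen.

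Most cisplatin calls rest on the second batch, whose 4 PBS libraries stand apart by ribosomal RNA-like transcripts. Fewer calls without these libraries cannot show that they made the calls, since only the first batch then remains in both PBS groups. If these libraries alone made the calls, first-batch fold changes would be expected at 0.208 of those in the second, the ratio of the batches' differences in that share on the log2 scale (−0.479 and −2.305). Outside the choroid plexus, and without pericytes (no first-batch value), the slope over 7416 genes called in the second batch was 0.379. The other 2 splits of the 4 first-batch libraries gave slopes up to 0.226 in size. In oligodendrocytes the slope of 0.552 (other splits up to 0.264) exceeds 0.208 by more than those splits. This argues against these libraries as the whole source there, as far as 2 other splits can show. In endothelium (0.356, 0.134), astrocytes (0.353, 0.174), microglia (0.334, 0.127), neurons (0.249, 0.384) and OPCs (0.219, 0.088) the excess is near or below those splits. Drug and library quality cannot be told apart there. Immune cells had a slope of 0.573 (other splits up to 0.106) over 8 such genes, too few to weigh. In the choroid plexus 26.4% of the genes called in the second batch had the same sign in the first, with a slope of −0.954. Neither these libraries, for which 0.208 would be expected, nor a drug effect common to both batches gives such a reversal. The source of its calls stays open, and the first-batch PBS libraries held 29 and 18 such cells. For the glucocorticoid response genes of oligodendrocytes the mean in the first batch was 2.175, where 0.356 would be expected from the 1.715 of the second (difference 1.819, SE 0.482 over 14 members). Of the 14, 11 were higher in both. The SE is taken over genes of the same 4 first-batch libraries and does not measure the spread between libraries. No other split was set beside it, so the values argue against these PBS libraries as the source only as far as 1 split can show.

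Stimulation raised 10 called glucocorticoid response genes in oligodendrocytes of cisplatin mice, for which glucocorticoid signalling is a biological candidate explanation that was not tested. RNA from other cell types stays open by the bound written beforehand, since markers of neurons reached 6.36% of their own level in these cells where the bound was 10 times below the 52.6% needed. Against the markers of microglia, astrocytes, endothelium, pericytes, neurons and choroid plexus, 9 of the 10 called members needed over 10 times the share found (median 18.95 times), which argues against RNA from these 6 types for them, but Mt2 needed 5.99 times and stays open, as does RNA from OPCs, immune cells and the rarer types, which were not tested. Doublets are argued against, since a Cdkn1a UMI was found in 55.6 to 69.4% of oligodendrocytes of the Cisplatin stim libraries without their deepest cells, at most 3.08% in PBS libraries and at most 3.85% of neurons in any library (median depths in Cisplatin stim 2 of 7608 and 2886 UMIs), and, thinned to 2000 UMIs, in 27.9 to 58.6% of Cisplatin stim, 3.63 to 7.91% of Cisplatin nonstim and at most 1.18% of PBS oligodendrocytes. Damaged cells are argued against too, since without cells over 10% mitochondrial UMIs 8 of the 10 stayed called and their mean log2 fold change went from 1.605 to 1.494.

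Thinning left out 121 shallower oligodendrocytes of PBS nonstim, 159 of PBS stim, 123 of Cisplatin nonstim and 43 of Cisplatin stim.

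The 17 interaction calls differ between PBS and cisplatin mice by the interaction test itself, and 4 of their 13 genes (30.8%) are near copies of other genes against 1.35% of all tested genes (Fisher's exact test, p = 2.1e-05). Reads shared between near copies may therefore account for Gm2000 (2.33 in microglia and 2.17 in oligodendrocytes), Rpl10-ps3 in microglia (2.72), Gm11808 in oligodendrocytes (1.39) and Rps27rt in neurons (3.2). RNA from choroid plexus cells is a candidate source of the Ttr calls (−4.01 in astrocytes, −5.38 in OPCs, −4.78 in pericytes), since 5 other choroid plexus markers held 216 UMIs in these cells where 177 would be expected from Ttr, a ratio of 1.22 (1.06 to 1.39, Poisson). The remaining calls stay open for both a biological and a technical reading, and chance is not excluded, since 16 of 60 splits of the libraries, the real one included, gave at least 17 calls and another gave 82. That split sets Cisplatin nonstim 3, Cisplatin stim 2 and Cisplatin stim 3 against Cisplatin nonstim 1, Cisplatin stim 1 and Cisplatin nonstim 2, and PBS nonstim 3, PBS stim 2 and PBS stim 3 against the other PBS libraries, and 13 of the 16 likewise put both first-batch libraries of an arm on 1 side, as 35 of the 60 do, which points to a structure of the samples that includes the batch; of the 25 others 3, the real one included, gave at least 17 (highest other 33), and the second batch alone gave 69.

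The other interaction calls reported were Gstp1 at −2.45 in microglia and −1.66 in oligodendrocytes, Plin4 at 2.5, Apod at 0.83, Scrg1 at 2.15, Usp50 at 2.21 and Nkain1 at −1.16 in oligodendrocytes, and Nrarp at 2.39 in pericytes (log2 differences). Fibroblasts, which enter no comparison, made up 0.759 ± 0.512% of cells in cisplatin libraries and 0.0968 ± 0.0787% in PBS libraries (SD, n = 6 each), with 62 of the 72 cells in cisplatin libraries (exact two-sided permutation within batches with all libraries taken as independent, p = 0.00952).

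Averaged over stimulation, 1 of 60 drawn splits of 200 possible ones gave as many gene calls as the real one (6757), and the highest other, 3774, exchanges the first-batch labels of cisplatin and PBS. In fits of the 2 arms over 8 types the second batch gave 11681 calls and the first 460 (387 in choroid plexus). For shares of cell types 1 of 60 splits, the real one, gave 3 calls and the highest other 2. These splits treat all libraries as independent. Same-numbered libraries of an arm may deviate together, more weakly in the PBS arm, and for shares this was not measured. The 10 splits keeping such pairs are too few for a share under 0.05. Of them 1 reached the 6757 gene calls (highest other 3774), 3 the 43 lists (46) and 2 the 3 shares (4). For lists 3 of 60 splits gave at least 43 (highest other 48), and 15 of 60 reached the interaction's 32 (highest other 49). Chance is not excluded for either.

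The comparisons of 3 against 3 libraries have 10 splits, too few for a share under 0.05. Cisplatin without stimulation gave 1142 gene calls, reached by 1 split, with 909 as the highest other, which exchanges the first-batch libraries. It gave 34 list calls, reached by 3 splits (highest other 37), and 2 share calls, reached by 2 (highest other 3). Stimulation in cisplatin mice gave 136 gene calls and 40 list calls, each reached by 1 split, with 73 and 38 as the highest others. Of its 4 splits that part all 3 same-numbered pairs, the highest other gave 7 gene calls, and for stimulation in PBS mice 3; the remaining 6 splits part 1 pair and keep the others together. Stimulation in PBS mice gave 0 gene calls by edgeR (1992 tests at an unadjusted p under 0.05, 7 calls by DESeq2, 0 by limma-voom) with 20 as the highest other, and a count of 0 is reached by any split. Its 9 list calls were reached by all 10 splits, with 39 as the highest other.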

How the results depend on the processing

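The ribosomal RNA-like covariate, each batch alone, the fits without near copies and those without the PBS or the Cisplatin stim libraries of the second batch were chosen after the data were seen. Fits without those libraries leave only the first batch in the groups concerned. The covariate separates the drug arms in the second batch. Calls lost in these fits can therefore come from lost power. Of 339 alternatives to the counts of calls and the comparison of stimulation with cisplatin effects, 242 stayed within 1.5 times or within the spread, 47 were lower, 48 higher, 2 moved and 0 changed sign. Of 5250 alternatives to 214 named genes, lists and shares, 4442 kept their direction and side of the threshold, 780 lost the call, 8 gained one and 20 changed sign. The cause was not tested except where named. Of the named results 95 of 156 lost their call with the covariate, 83 of 146 without the second-batch PBS libraries, 80 of 156 with no batch term, 35 of 156 without the second-batch Cisplatin stim libraries, 30 of 156 by DESeq2, 12 of 156 by limma-voom and 12 of 155 in the second batch alone.

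Gene calls for cisplatin without stimulation (1142) became 152 with no batch term, 2582 with no filter on low counts, 4354 with at least 30 cells, 25 with the covariate, 6895 in the second batch alone and 142 without its PBS libraries. With at least 30 cells choroid plexus alone made 3222 calls. Of the 142, 36 are among the 1142, and of the 25, 8 are. Stimulation in cisplatin mice (136) gave 15 with no batch term, 699 with no filter, 635 without the second-batch Cisplatin stim libraries, 212 without the second-batch PBS libraries and 205 with the compared groups alone. Stimulation in PBS mice (0 by edgeR, 1992 tests at an unadjusted p under 0.05) gave 7 by DESeq2, 0 by limma-voom, 169 with no filter, 13 with at least 30 cells, 6 without cells above the 95th percentile of UMIs, 12 with the covariate, 27 in the second batch, 2 and 5 without its Cisplatin stim and PBS libraries and 73 with the compared groups alone. The interaction (17) gave 0 with no batch term by edgeR, 10 by limma-voom, 341 with no filter, 36 with at least 30 cells, 26 without the deepest cells, 34 with the covariate, 69 in the second batch and 323 without its Cisplatin stim libraries. Cisplatin averaged over stimulation (6757) gave 3975 with no batch term, 254 with the covariate, 12467 in the second batch, 460 in the first (2 arms, 8 types), 3117 without the second-batch Cisplatin stim libraries and 997 without its PBS libraries.

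With an estimated correlation 0 lists passed in each of the 5 comparisons. By fry 1 passed for cisplatin without stimulation, 0 for stimulation in cisplatin mice, stimulation in PBS mice and the interaction, and 21 for cisplatin averaged. In the second batch alone 21 lists passed for stimulation in cisplatin mice, 29 for stimulation in PBS mice and 20 for the interaction, and with no filter 19 passed for stimulation in PBS mice. Shares gave 1 call with no batch term and 1 in the second batch alone, for cisplatin without stimulation and averaged.

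Leaving out 1 library at a time gave 236 (without Cisplatin nonstim 2) to 3223 (without PBS nonstim 1) gene calls for cisplatin without stimulation, 49 to 167 for stimulation in cisplatin mice, 1 to 13 for stimulation in PBS mice, 3 to 41 for the interaction and 3732 to 8970 for cisplatin averaged. Lists ranged over 31 to 41, 29 to 42, 8 to 26, 14 to 40 and 35 to 48, shares over 0 to 3 and 1 to 4 for cisplatin without stimulation and averaged and 0 to 0 elsewhere, and the correlation of cisplatin and stimulation effects over −0.451 to −0.167. Of 58 named calls for cisplatin without stimulation 36 held in each such fit, of 31 for stimulation in cisplatin mice 6 (Cdkn1a, Tspan4, Plin4, Cxcl12, Shtn1 and Apod in oligodendrocytes), of 16 named for the interaction 1, and of 47 for cisplatin averaged 44, the others being Slc35f1 in choroid plexus and Vim and Fbln5 in astrocytes, each lost without Cisplatin nonstim 2.

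Signs changed for Hist1h4h in microglia (0.483 without the second-batch PBS libraries) and AY036118 in neurons (0.05 with the covariate), both for cisplatin averaged. AY036118 is itself part of the covariate, so its change there was built in. For cisplatin without stimulation the covariate gave −0.234 for the inflammatory list in endothelium and 0.576 for the cell cycle list in OPCs, which ranged over −1.06 to 0.042 (without PBS nonstim 3) when 1 library was left out. The disease-associated list in microglia with stimulation was −0.002 in the second batch and −0.107 (without Cisplatin stim 1) to 0.448 when 1 library was left out. For cisplatin averaged the cell cycle list in OPCs was 0.316 with the covariate and the homeostatic astrocyte list 0.018 in the second batch. For 2 lists whose mean and test differ in sign the direction of the test changed. The complement list in microglia had means of 0.048 with no batch term, −0.002 with the covariate and 0.025 to 0.066 without 1 library. The blood-brain barrier list had 0.015 with no batch term and by fry, 0.028 with the covariate and −0.012 to 0.029 without 1 library.

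With the replicate number as a block the gene calls were 990, 114, 0 (edgeR), 21 and 5552 for the 5 comparisons in the order above. Where the numbers pair the libraries, within each drug arm, the block changed no named call other than Hist1h2ap in microglia and Ttr in astrocytes. Between PBS nonstim and Cisplatin nonstim the deviations correlated at 0.417, 0.173 and −0.028. There 3 of 6 libraries correlated best with their own number (PBS arm 4, cisplatin arm 6). These libraries were taken to share only a number, and with the block Fkbp5 in astrocytes had edgeR adjusted p = 0.0504 for cisplatin without stimulation. The alternative for values in another unit was not run, since the values are counts, and the fit on compared groups alone does not exist for the interaction and the average. The number of cells limits rare types: ependymal cells, fibroblasts and progenitors had too few per library for gene tests.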

Other observations

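The genes in this part were chosen after their values were seen. Over the 9 tested cell types, cisplatin averaged over stimulation raised Rbm3 in 8 and Cirbp in 7, both RNA-binding proteins induced by mild cold. The endoplasmic reticulum chaperone Hsp90b1 fell in 6 types and the chaperones Hsp90ab1 and Dnaja1 in 4 each. In oligodendrocytes Rbm3 was at 1.73 ± 0.20, Cirbp at 1.15 ± 0.13 and Hsp90b1 at −0.78 ± 0.10 (edgeR adjusted p = 4.55e-06, 3.12e-06 and 1.21e-05). Within the first and the second batch Rbm3 was at 1.33 ± 0.55 and 1.93 ± 0.15 there, and Hsp90b1 at −1.03 ± 0.23 and −0.63 ± 0.10. In astrocytes Rbm3 was at 0.96 ± 0.21 and 1.21 ± 0.13 in the 2 batches, and Hsp90b1 at −0.87 ± 0.16 and −0.61 ± 0.10. In choroid plexus Hsp90b1 had opposite signs, 1.58 ± 0.31 in the first and −1.31 ± 0.14 in the second. Dnaja1 in oligodendrocytes was at −0.02 ± 0.17 in the first batch and −0.59 ± 0.07 in the second.

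The glutathione transferase Gstm1 rose in 7 types and the sulfotransferase Sult1a1 in 6, while Hist1h4d fell in 8 and Hist1h1e in 6. The oligodendrocyte genes Mbp and Mobp and Ptgds were called higher in 5 types each and the choroid plexus marker Ttr in 8.

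The authors' cluster 19, 136 cells among the neurons led by Reln, Ndnf and Lhx1, made up 0.382% of cells in cisplatin libraries and 0.87% in PBS libraries on average. The log2 difference of −1.48 ± 0.56 did not pass over the clusters (edgeR adjusted p = 0.0787).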
